A study of Saccharomyces cerevisiae with 12 samples.

How the data were processed

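RNA from 12 yeast samples was sequenced at 4 time points, with n = 3 libraries each: quiescent cells, cells 30 min and 240 min after return to fresh medium, and logarithmically growing cells. Per the labels' protocols, RNA was extracted with QIAzol and bead beating, purified on columns, selected for poly(A) tails and made into libraries with the NEBNext Ultra II RNA kit. The libraries were sequenced from 1 end with 75 bp reads on a NextSeq 550. Whether reads were counted by strand is not given in the sources used here, so genes that overlap on opposite strands were treated as uncertain, as were near-identical paralogs and repeated genes. No spike-in RNA is named in the labels.

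The deposited table holds a normalised read count per gene and library, a signal that is never negative. Per the submitters' processing notes, STAR 2.5.2a, HTSeq 0.6.1, DESeq, DESeq2 and bedtools were used with the sacCer3 build, and the notes give the last 3 tools no version or role. The deposited values were whole multiples of the value of 1 read in every library (100% of values within a tolerance of 1e-06). The recovered reads, scaled again by the median-of-ratios size factors of DESeq, gave the same factors. The table was therefore treated as counts divided by a size factor per library. Of the 6120 genes, 124 were at 0 in all 12 libraries. Names and coordinates were taken from the NCBI R64 reference annotation, in which 6116 of the genes were found and 4 were not.

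The main test was limma 3.58.1 with an intensity trend (R 4.3.3) on log2(value + 1), over 5871 genes with a mean of at least 10 across the 12 libraries. Fold changes are on this scale, which as a rule understates the change of low genes. A value of 0 in quiescent replicate 1, where 1 read was worth 6.97 units, can instead overstate a rise. One model with the 4 groups gave 5 comparisons with 8 residual degrees of freedom. All tests were two-sided, with Benjamini-Hochberg adjustment within each comparison. A gene was called when its adjusted p was under 0.05, and counts of called genes that also changed at least 2-fold are given beside. The plan held a branch for each unit the table could have, and the branch for normalised values that are not logarithms was used. The groups, the tests, the gene lists, the rule for naming genes and the other settings to be tried were fixed before the data were examined.

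A total of 29 gene lists covered growth, carbon use, storage and stress, the cell cycle, biosynthesis, acetyl-CoA and histone acetylation, and other cell states. Each was tested with limma's camera at a preset inter-gene correlation of 0.01, with adjustment over the lists of a comparison, and again with an estimated correlation. Members were also counted after adjustment over the list alone. The genes named were the 10 largest increases and 10 largest decreases among called genes in each of the 3 successive comparisons. They needed a mean of at least 50 in the higher group and no overlap between the 3 libraries on each side, which chance gives for 10% of genes. The 3 largest each way were named for the comparisons of later groups with quiescent cells, the 5 largest among transient genes, and up to 4 members of a list. ACS1, ACS2, GCN5, ESA1, RPD3 and HDA1 were always named.

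The recovered reads numbered 1195233 to 5220494 in quiescent libraries, 7943459 to 11866340 at 30 min, 11572190 to 12428294 at 240 min and 13480102 to 15100323 in log phase. One read was worth 6.97 units in quiescent replicate 1, 1.46 and 1.70 in the other two quiescent libraries and 0.554 to 0.863 elsewhere. Low values in quiescent cells are therefore the least precise. The test was checked on simulated counts with 200 changed genes. It recovered 38% of 2-fold and 92% of 4-fold changes for 30 min against quiescent cells, 36% and 91% for 240 min against 30 min, and 37% and 91% for log phase against 240 min. Between 2 and 13 unchanged genes were called over the 5 simulated comparisons. The simulated counts had 1 spread per gene for all groups and no difference between replicate numbers. The median SD of log2 values was 0.42 in log phase and 0.21 to 0.25 in the other groups. The simulation leaves this out, so its figures for log phase may not hold for the real libraries. No pair of libraries of a group was alike within sampling noise, the lowest chi-square per degree of freedom being 3.77.

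Replicate numbers come from the labels, which do not say what they mark. Deviations from the group means correlated between all 18 pairs of libraries with the same number (0.134 to 0.582, across genes). For replicate 2 of different groups they correlated at 0.134 to 0.394, no higher than replicate 2 with replicate 3. Pairing of replicates 2 and 3 by number is therefore not shown. The main test has no block, and the replicate block is an alternative setting. Replicate 1 also stood apart from replicates 2 and 3 at all time points. Deviations correlated at -0.604 to -0.197 between replicate 1 and the others, negative in part through centring on the mean of 3 libraries. Between replicates 2 and 3 of different groups the deviations correlated at 0.210 to 0.553. Values are therefore given within replicate 1 and within replicates 2 and 3 for called results that turn on them and for some lists that were not called. Values with the replicate as a block are given where a call of a list or always-named gene changes. They are also given for the counts of called genes in each comparison.

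The settings fixed in advance were TMM and total-count scaling, no filter, a minimum mean of 100, a pseudocount of 5, the replicate block, a model of only the 2 groups compared, DESeq2 1.42.0 on the recovered reads, camera with an estimated correlation, and each library left out. The others were chosen after seeing the data: edgeR 4.0.16 on the recovered reads without and with the block, replicates 2 and 3 alone, and camera with both the block and an estimated correlation. On replicates 2 and 3 alone, with 2 libraries per group, camera was run with the preset correlation only. Total-count scaling moved the median log2 change of all tested genes. It was 0.18 for 30 min against quiescent cells, -0.46 for 240 min against 30 min, -0.28 for log phase against 240 min, and -0.18 and -0.42 for 240 min and log phase against quiescent cells. With the deposited scaling the medians were -0.07, -0.01, -0.01, 0.01 and 0.05, and all changes below are relative to these. No called list's median changed sign with TMM or total-count scaling. Tables and plots were made with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.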

Results

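The poly(A) RNA of budding yeast (Saccharomyces cerevisiae, strain pJD47) was sequenced at 4 time points around the exit from quiescence, a reversible state in which starved cells stop dividing. Quiescent cells had been kept for 7 days in water with 10 mM deuterated acetate. Cells leaving quiescence were collected 30 min and 240 min after return to fresh liquid medium, and the last group was growing logarithmically in glucose medium. Each group had n = 3 libraries, called biological replicates in the labels. The labels do not say whether these were separate cultures throughout, so the spread between libraries may in part be technical. The p-values rest on a spread per gene pooled over all 12 libraries, not on that of the compared groups alone. Log phase had the widest spread, so the p-values of comparisons with log phase may be too small. Depth ran from 1195233 recovered reads in quiescent replicate 1 to 15100323 in log-phase replicate 3. Values are normalised read counts as mean ± SD over 3 libraries, and changes are log2 fold changes ± SE with the adjusted p of limma. Coordinates are those of the R64 reference, and genes named with coordinates are protein coding unless stated.

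The first 4 principal components of the log2 values held 56.3%, 20.9%, 10.9% and 5.03% of the variance. The median SD of a gene's log2 values within a group was 0.25 in quiescent cells, 0.21 at 30 min, 0.23 at 240 min and 0.42 in log phase. Log-phase replicate 1 differed from the mean of log-phase replicates 2 and 3 by a median of 0.639, while the latter differed from each other by 0.209. At the other time points replicate 1 differed by 0.331 to 0.388 and replicates 2 and 3 by 0.0678 to 0.130.

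**Figure D1:**
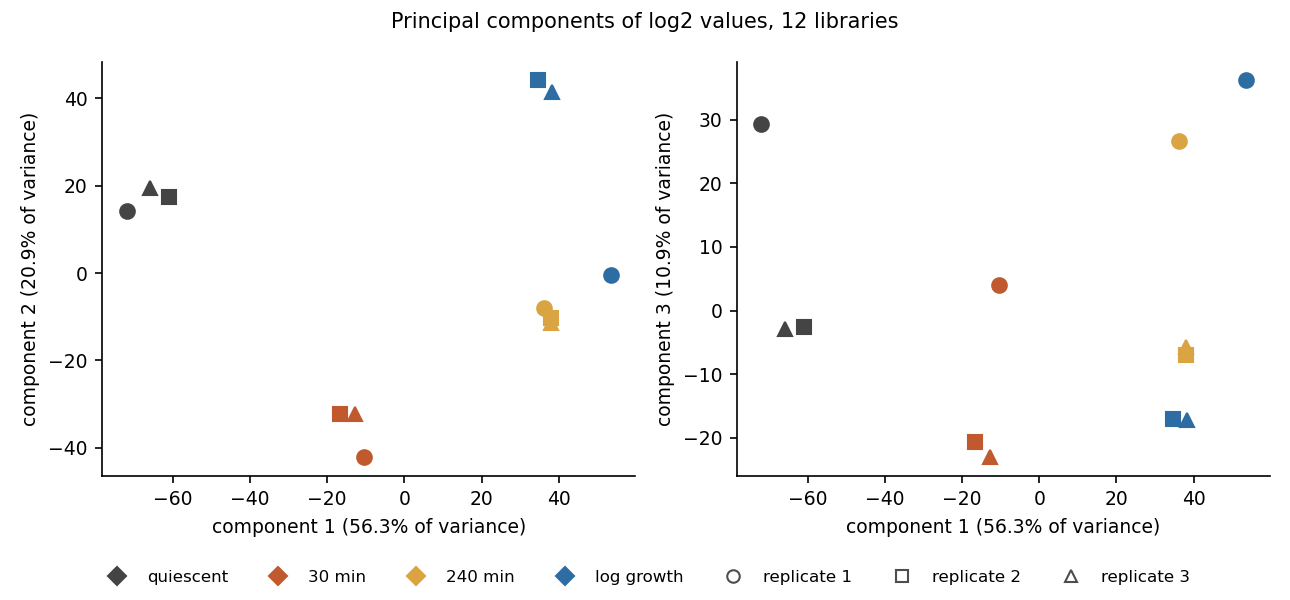
Scores of the 12 libraries on principal component 1 against components 2 and 3 of the log2 values. Colours mark the time points and symbols the replicate numbers, and each axis gives the share of variance (56.3% on the first). Log-phase replicate 1 has a score of -0.383 on the second component and log-phase replicates 2 and 3 have scores of 44.1 and 41.5.

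The first comparison covered the initial 30 min of exit. Genes for building ribosomes rose, and genes for the use of acetate and fatty acids and for storage carbohydrate fell (adjusted p = 0.123, 0.387, 0.0477 and 0.606 with an estimated correlation). The nucleolar protein gene NSR1 (YGR159C, chromosome VII, 806412 to 807656, minus strand) rose from 1064 ± 191 to 10243 ± 844 (log2 3.28 ± 0.24, adjusted p = 8.42e-06). POX1, the acyl-CoA oxidase of peroxisomal β-oxidation (YGL205W, chromosome VII, 108158 to 110404, plus strand), fell from 5484 ± 1733 to 741 ± 165 (log2 -2.87 ± 0.24, adjusted p = 1.44e-05). SSA4, a heat-inducible Hsp70 chaperone (YER103W, chromosome V, 364589 to 366517, plus strand), rose from 2628 ± 926 to 41287 ± 8825 (log2 4.02 ± 0.89, adjusted p = 0.00322). Of the 5871 genes tested, 1211 rose and 1394 fell, of which 806 and 916 changed at least 2-fold. With total-count scaling the split was 1670 higher and 978 lower.

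The 10 largest increases were those of ANS1, snR18, FEX2, BSC1, ZRT1, SSA4, AQR1, YAR1, YFR032C-B and JJJ3, with log2 changes up to 4.98 and adjusted p of 1.10e-05 to 0.00322. ANS1 (YHR126C, chromosome VIII, 359702 to 360181, minus strand) rose from 34.5 ± 7.08 to 1122 ± 206. The zinc transporter gene ZRT1 rose from 302 ± 204 to 4617 ± 65.7, and YAR1, whose product escorts the ribosomal protein Rps3, from 578 ± 35.8 to 7875 ± 870. FEX2, a fluoride exporter gene, and BSC1 were at 0 in quiescent replicate 1, where 1 read was worth 6.97 units. The small nucleolar RNA snR18 lies in an intron of EFB1 (chromosome I, 142367 to 142468, plus strand), and its reads cannot be separated from those of unspliced EFB1. The 10 largest decreases were those of snR14, SPG1, RGI2, POX1, POT1, GPX2, snR6, RDN5-1, CDC31 and CTA1, with log2 changes down to -4.04 and adjusted p of 6.10e-06 to 0.0126. CDC31, the yeast centrin gene (chromosome XV, 811008 to 811493, plus strand), fell from 10836 ± 1484 to 1541 ± 51.4. SPG1 was no longer called without 30 min replicate 1 (log2 -2.84, adjusted p = 0.0508). The U4 and U6 small nuclear RNAs (snR14, snR6) and the 5S ribosomal RNA (RDN5-1) have no poly(A) tail as a rule, and RDN5-1 is 1 of several near-identical copies.

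Among 135 ribosome biogenesis genes, 116 rose, 2 fell and 17 did not pass (125 and 2 adjusted over the list alone), with a median log2 change of 1.80 (camera adjusted p = 1.26e-32). NOP14 rose by 3.15 ± 0.21, SPB1 by 2.99 ± 0.25 and CIC1 by 2.97 ± 0.21. Of 19 subunits of RNA polymerases I and III, 14 rose (14 adjusted over the list alone; median 1.60, adjusted p = 6.27e-07), among them RPA12 (2.70 ± 0.57) and RPC19 (2.46 ± 0.36). Of 54 translation factors and tRNA synthetases, 35 rose and 1 fell (37 and 1 adjusted over the list alone; median 1.02, adjusted p = 5.01e-09), with MES1 up by 2.25 ± 0.22 and CAM1 at -1.85 ± 0.21. With an estimated correlation these 3 lists had adjusted p = 0.123, 0.0904 and 0.0904. The 138 cytosolic ribosomal protein genes, many of them near-identical pairs that share reads, did not move as a list (7 rose and 2 fell, 2 rose adjusted over the list alone; median 0.07, adjusted p = 0.376). Of 72 mitochondrial ribosomal protein genes, 10 rose and 5 fell (9 and 4 adjusted over the list alone; adjusted p = 0.256).

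Of 25 genes of gluconeogenesis, the glyoxylate cycle and acetate use, 19 fell (21 adjusted over the list alone; median -1.78, adjusted p = 5.75e-08, and adjusted p = 0.387 with an estimated correlation). ADY2, an acetate transporter gene (YCR010C, chromosome III, 132273 to 133124, minus strand), fell from 86196 ± 8518 to 14361 ± 4203. The carnitine acetyltransferase gene YAT1 changed by -2.63 ± 0.44, the alcohol dehydrogenase gene ADH2 by -2.53 ± 0.40 and the lactate permease gene JEN1 by -2.36 ± 0.45. Of 15 β-oxidation genes, 13 fell (14 adjusted over the list alone; median -2.24, adjusted p = 5.75e-08, and adjusted p = 0.0477 with an estimated correlation), including POT1 (-2.84 ± 0.38), CTA1 (-2.74 ± 0.25) and ECI1 (-2.65 ± 0.24). With the block and an estimated correlation that list had adjusted p = 0.334. Among 17 trehalose and glycogen genes, 12 fell (15 adjusted over the list alone; median -1.51, adjusted p = 6.96e-04, and adjusted p = 0.606 with an estimated correlation). TPS1, the trehalose-6-phosphate synthase gene, fell from 13105 ± 4926 to 2285 ± 463. The citric acid cycle list did not pass (3 of 15 rose and 8 fell, 3 and 9 adjusted over the list alone; adjusted p = 0.0790), but did with the replicate block (adjusted p = 0.0391, and adjusted p = 0.708 with the block and an estimated correlation). Glycolysis genes went both ways (4 of 21 rose and 5 fell, 4 and 4 adjusted over the list alone; adjusted p = 0.932), with GLK1 at -2.60 ± 0.49 and PFK1 at 1.27 ± 0.30. Of 18 hexose transporters 1 rose and 6 fell (1 and 6 adjusted over the list alone; adjusted p = 0.176). Of 37 nuclear genes of the respiratory chain 3 rose and 9 fell (3 and 8 adjusted over the list alone; adjusted p = 0.658).

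Of 39 general stress and heat shock genes, 4 rose and 20 fell (5 and 22 adjusted over the list alone; median -1.01, adjusted p = 0.00513, and adjusted p = 0.746 with an estimated correlation). TFS1 fell by 2.57 ± 0.47, while the mitochondrial chaperone gene HSP78 was at 2.47 ± 0.47. Of 29 autophagy genes, 2 rose and 11 fell (2 and 14 adjusted over the list alone; adjusted p = 0.00453, and adjusted p = 0.474 with an estimated correlation), with ATG8 at -2.46 ± 0.33 and ATG41 at 2.37 ± 0.27. The mitotic cyclin gene CLB2 rose from 80.2 ± 22.2 to 660 ± 291. In its G2/M cluster of 23 genes 12 rose (12 adjusted over the list alone; median 0.97, adjusted p = 7.70e-05, and adjusted p = 0.474 with an estimated correlation). Of 45 genes of G1/S and DNA replication, 15 rose and 2 fell (15 and 2 adjusted over the list alone; adjusted p = 0.00453, and adjusted p = 0.746 with an estimated correlation), for example SMC3 (1.67 ± 0.26) and CDC45 (1.60 ± 0.31). Of 18 mitotic exit and daughter separation genes, 7 fell (5 adjusted over the list alone; adjusted p = 0.0365, and adjusted p = 0.591 with an estimated correlation), led by the chitinase gene CTS1 (-2.08 ± 0.28). That list's call ended without quiescent replicate 1 (adjusted p = 0.123) or 30 min replicate 1 (adjusted p = 0.0512).

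Amino acid synthesis genes rose (27 of 59, with 8 falling; 27 and 8 adjusted over the list alone; median 0.50, adjusted p = 0.00347, and adjusted p = 0.565 with an estimated correlation). GDH1 rose by 2.71 ± 0.36, LEU1 by 2.30 ± 0.27 and the mitochondrial aminotransferase gene BAT1 by 2.18 ± 0.24, whereas its cytosolic counterpart BAT2 was at -2.21 ± 0.23. Lists that did not pass were methionine and sulfur (8 of 25 rose and 6 fell, 8 and 6 adjusted over the list alone; adjusted p = 0.542), ergosterol (6 of 23 rose and 9 fell, 7 and 10 adjusted over the list alone; adjusted p = 0.932) and purine synthesis (4 of 21 rose and 5 fell; adjusted p = 0.663). Neither did the proteasome (3 of 34 fell, 2 adjusted over the list alone; adjusted p = 0.663) or the histones (1 of 11 fell, 1 adjusted over the list alone; adjusted p = 0.663). The lists of other cell states, meiosis (10 of 38 rose and 10 fell; adjusted p = 0.607) and mating (3 of 24 rose and 7 fell, 2 and 7 adjusted over the list alone; adjusted p = 0.822), did not pass. The 6 mitochondrially encoded messenger RNAs fell (6 adjusted over the list alone; median -2.36, adjusted p = 0.00185, and adjusted p = 0.387 with an estimated correlation), with COX2 at -2.59 ± 0.41. Median and mean had opposite signs for the glycolysis and ergosterol lists and for both histone acetylation lists described next, all of them uncalled.

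For the enzymes named by the study's theme, transfer of acetyl groups on histones, the list of histone acetyltransferases and their complexes went both ways (10 of 37 rose and 4 fell, 10 and 4 adjusted over the list alone; adjusted p = 0.663). The deacetylase list did so too (6 of 34 rose and 8 fell, 5 and 7 adjusted over the list alone; adjusted p = 0.693). EAF3, a chromodomain subunit of the NuA4 acetyltransferase and the Rpd3S deacetylase (chromosome XVI, 608826 to 610031, minus strand), fell from 12866 ± 4581 to 3019 ± 313. HAT1 rose by 1.67 ± 0.25 and HST2 was at -1.69 ± 0.31. The deacetylase gene HDA1 rose from 329 ± 67.4 to 708 ± 110 (adjusted p = 0.00256) and the acetyltransferase gene GCN5 from 721 ± 44.6 to 998 ± 5.33 (0.47 ± 0.15, adjusted p = 0.0235). ESA1 (0.07 ± 0.26, adjusted p = 0.833) and RPD3 (0.05 ± 0.30, adjusted p = 0.913) were not called. Of 26 genes of acetyl-CoA supply and use, 2 rose and 17 fell (2 and 19 adjusted over the list alone; median -1.27, adjusted p = 1.93e-04, and adjusted p = 0.387 with an estimated correlation). Of the acetyl-CoA synthetases, ACS1 fell from 5124 ± 2984 to 954 ± 69.2 (-2.28 ± 0.32, adjusted p = 2.15e-04) and ACS2 rose from 424 ± 153 to 709 ± 158 (0.77 ± 0.26, adjusted p = 0.0300). The call of ACS2 was lost without quiescent replicate 2 (adjusted p = 0.119), quiescent replicate 3 (0.108) or 30 min replicate 1 (0.115). That of GCN5 was lost without quiescent replicate 2 (0.0813), 30 min replicate 2 (0.0692) or 30 min replicate 3 (0.0707). Some called lists had differing medians within replicate 1 and within replicates 2 and 3. Trehalose stood at -2.05 and -1.33, the G2/M cluster at 0.58 and 1.13, mitotic exit at -0.93 and -0.42 and amino acid synthesis at 0.38 and 0.59.

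**Figure D2:**
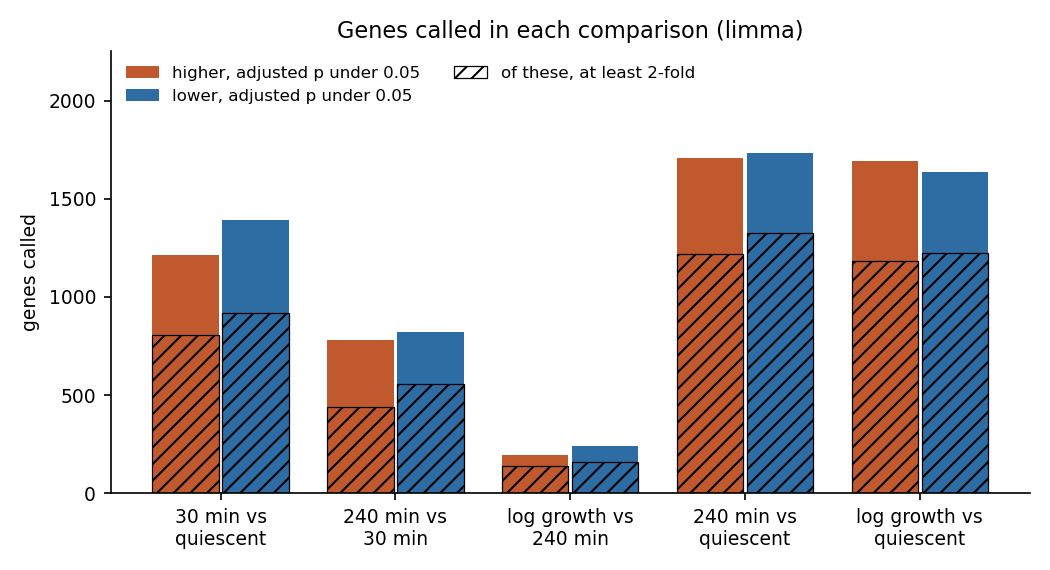
Bars give the number of genes called higher and lower by limma at an adjusted p under 0.05 in each of the 5 comparisons, and the hatched parts those that changed at least 2-fold. Log phase against 240 min has the fewest calls (192 higher and 240 lower) and 240 min against quiescent cells the most (1708 and 1734).

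The second comparison covered the time from 30 min to 240 min of exit. Genes of ribosomal proteins, glycolysis and daughter cell separation rose, and acetate genes fell (adjusted p = 0.0237, 0.0478, 0.0478 and 0.123 with an estimated correlation). CDC19, the main pyruvate kinase gene (YAL038W, chromosome I, 71786 to 73288, plus strand), rose from 10908 ± 1144 to 66699 ± 3888 (log2 2.62 ± 0.27, adjusted p = 6.15e-05). EGT2, a gene of cell wall separation after division (YNL327W, chromosome XIV, 24048 to 27173, plus strand), rose from 207 ± 66.4 to 2155 ± 345 (3.42 ± 0.27, adjusted p = 3.46e-05). BTN2, a protein sorting factor for misfolded proteins (YGR142W, chromosome VII, 772454 to 773686, plus strand), fell from 76206 ± 12405 to 3240 ± 1915 (-4.81 ± 0.55, adjusted p = 1.05e-04). In all 779 genes rose and 823 fell, of which 439 and 558 changed at least 2-fold. Total-count scaling gave 328 higher and 1941 lower. The counts fell to 516 and 495 without 30 min replicate 2, to 529 and 522 without 30 min replicate 3 and to 518 and 535 without 240 min replicate 3.

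The 10 largest increases were those of EGT2, YER138W-A, HXT1, CTS1, RPL9A, HTA2, GND1, ENO2, UTR2 and CSS1 (log2 2.76 to 3.42, adjusted p = 3.46e-05 to 0.00435). HXT1, the low-affinity glucose transporter gene (chromosome VIII, 290913 to 292625, minus strand), rose from 610 ± 73.6 to 5477 ± 399. YER138W-A is a short gene at 11.5 ± 8.50 and then 90.0 ± 31.6. The 10 largest decreases were those of ANS1, BTN2, YMR244W, FDH1, GAP1, MEP2, ECM13, snR18, SIP4 and LST8 (log2 -4.84 to -3.16, adjusted p = 3.46e-05 to 0.00360). GAP1, the general amino acid permease gene (chromosome XI, 515063 to 516871, plus strand), fell from 10214 ± 909 to 885 ± 379. The ammonium permease gene MEP2 changed by -3.52 ± 0.71, and SIP4, which encodes an activator of gluconeogenic genes, by -3.20 ± 0.28.

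Ribosomal protein genes rose between 30 min and 240 min, 122 of 138 (132 adjusted over the list alone), with a median of 2.08 (adjusted p = 9.84e-50, and adjusted p = 0.0237 with an estimated correlation). RPL9A rose by 3.04 ± 0.31 and RPS21B by 2.73 ± 0.26, with reads that may be shared with their paralogs. Ribosome biogenesis, by contrast, had 7 of 135 genes rising and none of these adjusted over the list alone by limma, and a median of 0.11 that turned to -0.35 with total-count scaling (adjusted p = 0.238). Of the translation factors 32 rose (35 adjusted over the list alone; median 0.93, adjusted p = 8.14e-13, and adjusted p = 0.0261 with an estimated correlation), among them GUS1 (1.81 ± 0.19). Of 21 glycolysis genes 14 rose and 1 fell (15 and 3 adjusted over the list alone; median 1.41, adjusted p = 6.76e-06, and adjusted p = 0.0478 with an estimated correlation), with ENO2 at 2.81 ± 0.37, TDH3 at 2.45 ± 0.31 and PGK1 at 2.29 ± 0.31. Of 23 ergosterol genes 13 rose (15 adjusted over the list alone; median 1.15, adjusted p = 2.51e-07, and adjusted p = 0.0261 with an estimated correlation), such as ERG13 (2.00 ± 0.30). Of 18 mitotic exit genes 10 rose (11 adjusted over the list alone; median 0.97, adjusted p = 7.21e-09, and adjusted p = 0.0478 with an estimated correlation), with CTS1 at 3.08 ± 0.28 and DSE4 at 2.60 ± 0.23. Of 11 histone genes, whose copies are near-identical, 5 rose (8 adjusted over the list alone; median 1.41, adjusted p = 0.00329, and adjusted p = 0.0478 with an estimated correlation), led by HTA2 (2.83 ± 0.28). With the replicate block and an estimated correlation, the ribosomal proteins had adjusted p = 0.0462 and the other lists of this paragraph were not called. Adjusted p was then 0.102 for translation, 0.0764 for histones, and 0.0993 for glycolysis, ergosterol and mitotic exit.

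Acetate and gluconeogenesis genes fell further, 21 of 25 (21 adjusted over the list alone; median -1.95, adjusted p = 2.64e-12, and adjusted p = 0.123 with an estimated correlation), for example CRC1 (-2.85 ± 0.27) and the malate synthase gene MLS1 (-2.73 ± 0.36). Of the β-oxidation genes 8 fell (10 adjusted over the list alone; adjusted p = 1.73e-04, and adjusted p = 0.0478 with an estimated correlation). Of 38 meiosis genes 16 fell (23 adjusted over the list alone; median -0.80, adjusted p = 7.62e-07, and adjusted p = 0.0261 with an estimated correlation), with MND1 at -2.46 ± 0.31. With the block and an estimated correlation adjusted p was 0.161 for β-oxidation and 0.0270 for meiosis. Of 39 stress genes 2 rose and 22 fell (3 and 22 adjusted over the list alone; median -1.20, adjusted p = 1.34e-06, and adjusted p = 0.381 with an estimated correlation), among them the small heat shock protein genes HSP26 (-2.99 ± 0.46) and HSP42 (-2.88 ± 0.43). SSA4 fell by 3.10 ± 0.89 (adjusted p = 0.0225), a call lost without 30 min replicate 2 (adjusted p = 0.0715), 30 min replicate 3 (0.0627) or 240 min replicate 1 (0.0909). Autophagy genes fell (10 of 29, 1 rising; 12 and 1 adjusted over the list alone; adjusted p = 3.68e-04, and adjusted p = 0.234 with an estimated correlation), with ATG41 at -2.87 ± 0.27. Of 59 amino acid genes 25 rose and 3 fell (31 and 3 adjusted over the list alone; median 0.87, adjusted p = 3.52e-08, and adjusted p = 0.123 with an estimated correlation), such as HIS4 (2.26 ± 0.27). Of 21 purine genes 6 rose (7 adjusted over the list alone; adjusted p = 0.00402, and adjusted p = 0.603 with an estimated correlation), such as IMD2 (2.69 ± 0.26). Of 25 methionine genes 2 rose and 9 fell (3 and 11 adjusted over the list alone; adjusted p = 0.00721, and adjusted p = 0.234 with an estimated correlation), such as STR3 (-2.57 ± 0.30). Mitochondrially encoded RNA fell (2 of 6, 4 adjusted over the list alone; adjusted p = 0.0340, and adjusted p = 0.424 with an estimated correlation), a call lost without 30 min replicate 2 (adjusted p = 0.0669) or 240 min replicate 1 (0.0659).

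Of the acetyl-CoA synthetases, ACS2 rose to 3096 ± 383 (2.14 ± 0.26, adjusted p = 1.65e-04) and ACS1 fell to 293 ± 10.7 (-1.70 ± 0.32, adjusted p = 0.00246). GCN5 (0.04 ± 0.15, adjusted p = 0.864), ESA1 (-0.43 ± 0.26, adjusted p = 0.255), RPD3 (0.08 ± 0.30, adjusted p = 0.869) and HDA1 (0.36 ± 0.24, adjusted p = 0.297) were not called. Neither were the acetyltransferase list (3 of 37 rose and 4 fell, 3 and 3 adjusted over the list alone; adjusted p = 0.343) and the deacetylase list (1 of 34 rose and 3 fell, 1 and 1 adjusted over the list alone; adjusted p = 0.565). EAF3 fell again, to 1516 ± 126 (adjusted p = 0.0114), and TRA1, a shared subunit of SAGA and NuA4, rose by 1.22 ± 0.19. In all 14 lists did not pass, with adjusted p of 0.108 to 0.922. Among them the trehalose and glycogen list had a median of 1.15 within replicate 1 and -0.69 within replicates 2 and 3 (adjusted p = 0.0347 alone, with the preset correlation). Ribosome biogenesis stood at -0.14 and 0.26 (0.00428), the G2/M cluster at 0.32 and -0.32 (0.0477) and the proteasome at -0.02 and 0.29 (0.00513). The genes called higher and lower, chosen from these same libraries, had medians of 1.16 and -1.24 within replicate 1 and 1.06 and -1.22 within replicates 2 and 3. Among called lists, mitotic exit stood at 1.62 and 0.87, purine synthesis at 0.97 and 0.49 and autophagy at -0.27 and -0.66.

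A total of 95 genes were called and at least 2-fold higher at 30 min than both in quiescent cells and at 240 min. Independent lists of the same sizes would share 76.6, and 100 simulated draws with unchanged groups and a shared 30 min group gave 0. The simulation leaves out the effects and the product of list sizes leaves out the shared libraries. The 5 with the largest sum of both changes were ANS1, YMR244W, snR18, BTN2 and SSA4. YMR244W (chromosome XIII, 757250 to 758317, plus strand) was at 411 ± 26.6, 3216 ± 738 and 137 ± 63.6 at the 3 successive times, and BTN2 at 13197 ± 1550, 76206 ± 12405 and 3240 ± 1915. Of the fixed lists, stress and meiosis held 3 transient genes each, and autophagy and the G2/M cluster 1 each. With total-count scaling 215 genes were transient.

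**Figure D3:**
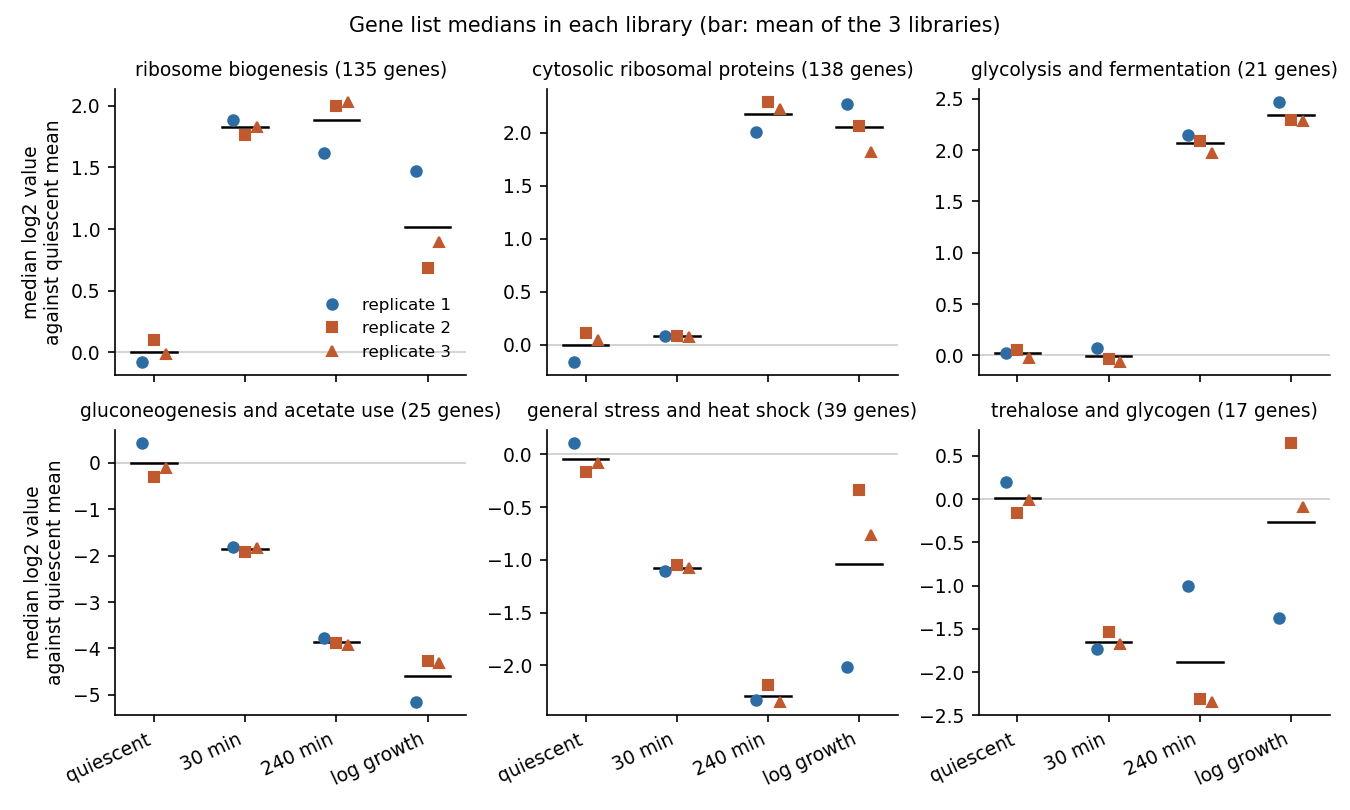
Median log2 value of 6 gene lists in each library against the quiescent mean, with replicate 1 in blue, replicates 2 and 3 in orange and a bar at the mean of the 3 libraries. Ribosome biogenesis stands at 1.76 to 1.88 by 30 min, while the ribosomal proteins are at 0.07 to 0.08 then and at 2.01 to 2.29 by 240 min.

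The third comparison set log-phase cells against cells 240 min into exit. The acetate transporter gene ADY2 and the carnitine acetyltransferase gene YAT1 were lower in log phase, as were ribosome biogenesis genes, and respiratory chain and stress genes were higher. With an estimated correlation these lists had adjusted p = 0.289, 0.196 and 0.331, and the stress list had a median of 0.20 within replicate 1 against 1.97 within replicates 2 and 3. YAT1 (YAR035W, chromosome I, 190193 to 192256, plus strand) stood at 1911 ± 429 by 240 min and at 149 ± 101 in log phase (-3.91 ± 0.45, adjusted p = 8.64e-04), and ADY2 at 2034 ± 616 and 152 ± 77.3 (-3.85 ± 0.41, adjusted p = 6.59e-04). TDH1, a glyceraldehyde-3-phosphate dehydrogenase isozyme gene that shares sequence with TDH2 and TDH3 (YJL052W, chromosome X, 338271 to 339269, plus strand), rose from 1650 ± 807 to 15267 ± 2239 (3.31 ± 0.31, adjusted p = 2.94e-04). The secreted glycoprotein gene YGP1 (chromosome XIV, 336545 to 337609, plus strand) rose from 852 ± 279 to 7168 ± 832 (3.11 ± 0.31, adjusted p = 4.65e-04). Of the genes tested 192 were higher and 240 lower, of which 138 and 158 at least 2-fold. With the replicate block the counts were 544 and 522, and with total-count scaling 112 and 693.

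These counts depended on single libraries and on which libraries gave the spread. They were 29 higher and 37 lower without 240 min replicate 2, 19 and 29 without 240 min replicate 3, 47 and 114 without log-phase replicate 2, and 41 and 59 without log-phase replicate 3. Without log-phase replicate 1 they were 1108 and 968. A model of only these 2 groups called 6 higher and 13 lower. The genes called higher and lower, chosen from these same libraries, had medians of 0.61 and -0.65 within replicate 1 against 1.45 and -1.41 within replicates 2 and 3.

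The 10 largest increases were those of EGO4, YER053C-A, TDH1, SPI1, YGP1, ALD3, RTC3, YRO2, STF2 and RTN2 (adjusted p = 2.94e-04 to 0.0464). Of these, EGO4, ALD3, RTC3, STF2 and RTN2 were no longer called without 240 min replicate 2 or 3 or log-phase replicate 2 or 3, and EGO4 and ALD3 also without 240 min replicate 1. Their adjusted p reached 0.199, 0.192, 0.101, 0.130 and 0.0941 in turn, and SPI1 had 0.0585 without 240 min replicate 3. In the model of only the 2 groups just TDH1 and YGP1 of these 10 were called, and the other 8 had adjusted p of 0.110 (YER053C-A and YRO2) to 0.206 (ALD3). The 10 largest decreases were those of LSO1, YAR035C-A, YAT1, ADY2, YHR054C, MAE1, DAL80, GDH3, SFC1 and CRC1 (log2 -5.15 to -2.30, adjusted p = 1.98e-06 to 0.00636), which include genes of the malic enzyme, a succinate-fumarate carrier and a carnitine carrier. In the model of only the 2 groups LSO1 (adjusted p = 0.0740), MAE1 (0.108), GDH3 (0.0848) and SFC1 (0.0538) were not called. LSO1 (chromosome X, 448477 to 448758, minus strand) held 8 reads over the 3 log-phase libraries and YAR035C-A (chromosome I, 192337 to 192417, minus strand) 6. YAR035C-A ends 80 bases from YAT1 on the opposite strand, so its reads may come from YAT1, and YHR054C (chromosome VIII, 213185 to 214249, minus strand) lies in the repeated CUP1 region.

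Of 135 ribosome biogenesis genes, 42 were lower in log phase (79 adjusted over the list alone; median -0.76, adjusted p = 3.00e-25, and adjusted p = 0.289 with an estimated correlation). The list's median was -0.21 within replicate 1 and -1.01 within replicates 2 and 3. RPF1 changed by -1.50 ± 0.29, and was not called without 240 min replicate 2 (adjusted p = 0.0671), 240 min replicate 3 (0.0734) or log-phase replicate 3 (0.0629), nor in the model of only the 2 groups (0.113). Of the polymerase I and III subunits 3 were lower (7 adjusted over the list alone; adjusted p = 1.01e-04, and adjusted p = 0.289 with an estimated correlation). Their medians were -0.09 within replicate 1 and -0.58 within replicates 2 and 3. The nuclear respiratory chain genes were higher, 20 of 37 (27 higher and 1 lower adjusted over the list alone; median 0.97, adjusted p = 8.29e-15, and adjusted p = 0.196 with an estimated correlation), with medians of 0.78 and 1.16 within replicate 1 and within replicates 2 and 3. QCR10 changed by 1.66 ± 0.28 and was not called without 240 min replicate 3 (adjusted p = 0.0502) or in the model of only the 2 groups (0.0902). Of 15 citric acid cycle genes 3 were higher (7 adjusted over the list alone; median 0.66, adjusted p = 4.14e-04, and adjusted p = 0.399 with an estimated correlation), at 0.46 within replicate 1 and 0.73 within replicates 2 and 3.

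Of 39 stress genes, 14 were higher in log phase (24 higher and 2 lower adjusted over the list alone; median 1.41, adjusted p = 1.99e-09, and adjusted p = 0.331 with an estimated correlation). The trehalose and glycogen genes were higher in the pooled test (4 of 17, 10 adjusted over the list alone; median 1.31, adjusted p = 1.35e-05, and adjusted p = 0.410 with an estimated correlation). Within replicate 1 this did not hold (median -0.55), while replicates 2 and 3 had a median of 2.10 (adjusted p = 3.14e-08 alone, with the preset correlation). Autophagy differed likewise (1 higher and 1 lower of 29, 4 and 2 adjusted over the list alone; adjusted p = 0.0136, and adjusted p = 0.420 with an estimated correlation), at -0.10 within replicate 1 and 0.55 within replicates 2 and 3 (adjusted p = 0.00248 alone). Mitotic exit (3 higher of 18, 6 higher and 1 lower adjusted over the list alone; adjusted p = 0.0468, and adjusted p = 0.456 with an estimated correlation) was at -0.00 within replicate 1 and 0.66 within replicates 2 and 3 (adjusted p = 0.0985 alone). Autophagy was not called without 240 min replicate 2 (adjusted p = 0.0511) or log-phase replicate 2 (0.0533). Mitotic exit was not called without 240 min replicate 2 (0.138), 240 min replicate 3 (0.131) or log-phase replicate 1 (0.387).

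The acetate list was lower, with 1 of 25 higher and 10 lower (3 and 13 adjusted over the list alone; median -1.20, adjusted p = 2.89e-04, and adjusted p = 0.420 with an estimated correlation), and its medians were -1.42 within replicate 1 and -0.74 within replicates 2 and 3. Without log-phase replicate 1 this call was lost (adjusted p = 0.162). So were those of glycolysis (2 of 21 higher and 1 lower, 6 and 1 adjusted over the list alone; adjusted p = 0.0102, then 0.0661), methionine (4 of 25 lower, 4 adjusted over the list alone; 0.0102, then 0.234), mating (3 of 24 higher, 3 adjusted over the list alone; 0.0134, then 0.581), meiosis (1 of 38 higher and 4 lower, 2 and 5 adjusted over the list alone; 0.0373, then 0.234) and mitochondrially encoded RNA (3 of 6 lower, 4 adjusted over the list alone; 0.00129, then 0.0687). Meiosis also had adjusted p = 0.0639 and 0.0714 without 240 min replicate 2 or 3. With an estimated correlation adjusted p was 0.331 for glycolysis, methionine, meiosis and mitochondrially encoded RNA and 0.420 for mating. Amino acid synthesis was lower (4 of 59, 4 adjusted over the list alone; adjusted p = 0.00293, and adjusted p = 0.420 with an estimated correlation), with GDH3 at -2.41 ± 0.35. Its median was at -0.02 within replicate 1 and -0.42 within replicates 2 and 3, and the methionine and mating lists stood at -0.43 and -0.24 and at 0.68 and 0.20.

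ACS1 (-0.01 ± 0.32, adjusted p = 0.990), GCN5 (0.13 ± 0.15, adjusted p = 0.625), RPD3 (-0.11 ± 0.30, adjusted p = 0.841) and HDA1 (0.12 ± 0.24, adjusted p = 0.777) were not called between 240 min and log phase. ACS2 (0.53 ± 0.26, adjusted p = 0.228) and ESA1 (-0.71 ± 0.26, adjusted p = 0.116) were not called, but were with the replicate block (adjusted p = 0.0436 and 0.0240). The acetyltransferase list had 1 of 37 genes higher and 1 lower (1 lower adjusted over the list alone; adjusted p = 0.443), and the deacetylase list had adjusted p = 0.878. With the block the histone list (median 0.40) went from adjusted p = 0.213 to 0.0408 and the mitochondrial ribosomal protein list (median 0.12) from 0.0832 to 0.0495. With the block and an estimated correlation these had adjusted p = 0.377 and adjusted p = 0.460. The 14 lists that did not pass had adjusted p of 0.0832 to 0.976, and for hexose transporters and deacetylases the median and the mean had opposite signs. Within replicate 1 and within replicates 2 and 3, the G1/S list stood at 0.43 and -0.53 (adjusted p = 4.13e-05 in the latter alone, with the preset correlation). The ribosomal proteins stood at 0.30 and -0.28 (0.0158), translation at 0.10 and -0.23 (0.0238) and the hexose transporters at -0.79 and 0.53 (0.123).

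**Figure D4:**
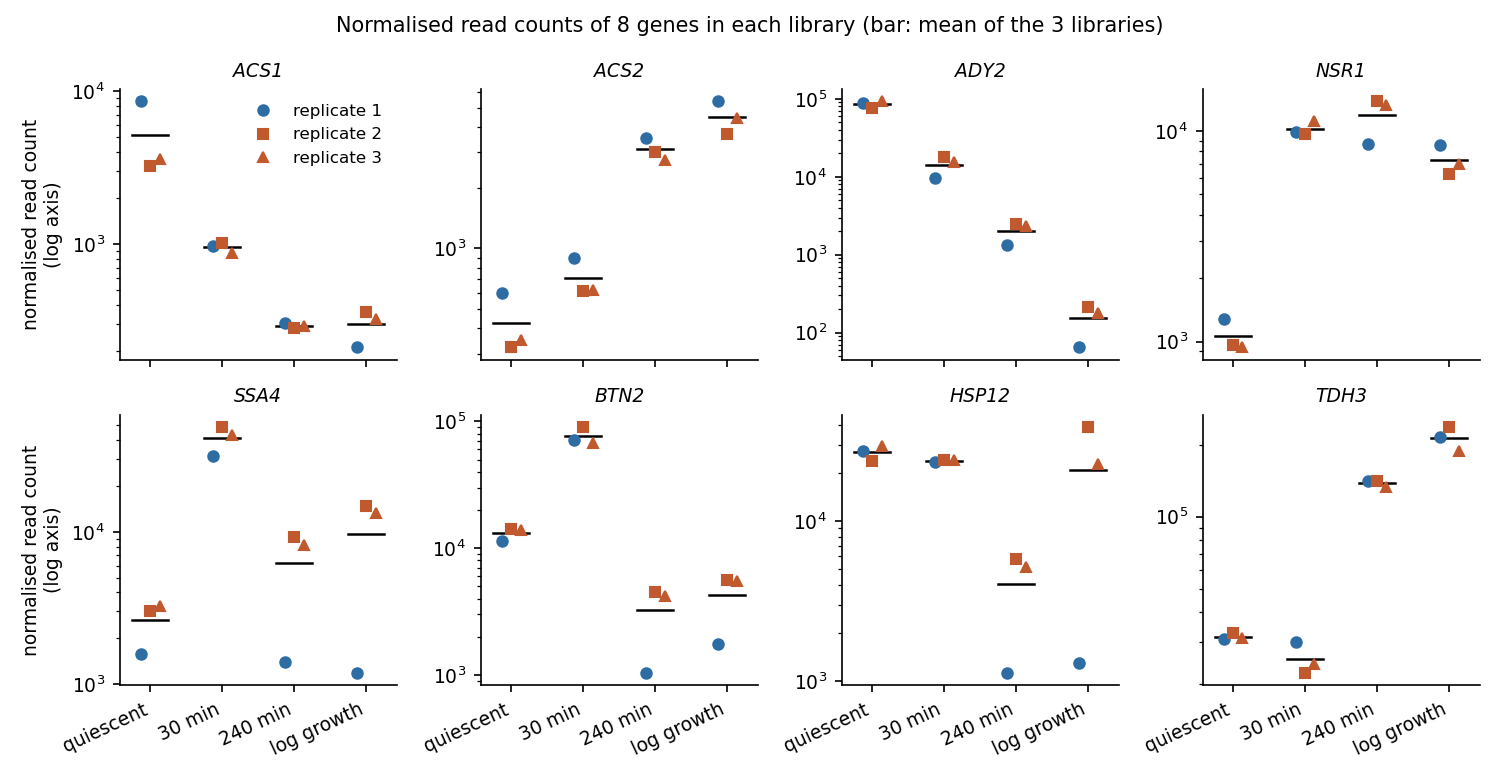
Normalised read counts of 8 genes in each library on a log axis, with replicate 1 in blue, replicates 2 and 3 in orange and a bar at the mean of the 3 libraries. ADY2 falls from a mean of 86196 in quiescent cells to 152 in log phase, and HSP12 stands at 1297 in log-phase replicate 1 against 38800 and 22735 in log-phase replicates 2 and 3.

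The last comparisons set 240 min and log phase against quiescent cells. The proton pump gene PMA1 (YGL008C, chromosome VII, 479910 to 482666, minus strand) rose from 5465 ± 1395 in quiescent cells to 97576 ± 32253 in log phase (4.12 ± 0.40, adjusted p = 4.27e-06), and ADY2 fell by 9.30 ± 0.41 (adjusted p = 1.81e-08). By 240 min, BAT1 had risen by 3.64 ± 0.24 and the cell wall gene UTR2 by 3.55 ± 0.36. At 240 min 1708 genes were higher and 1734 lower than in quiescent cells (1217 and 1326 at least 2-fold), and in log phase 1691 and 1635 (1183 and 1226). Total-count scaling gave 978 higher and 2387 lower in log phase. Genes called higher and lower, chosen from these same libraries, had medians of 1.34 and -1.55 within replicate 1 and 1.35 and -1.46 within replicates 2 and 3 at 240 min, and 1.40 and -1.68 against 1.27 and -1.37 in log phase. The largest increases at 240 min were those of BSC1 (5.28 ± 0.88), BAT1 and UTR2, and in log phase those of PMA1, MRH1 (3.96 ± 0.24) and YHL018W (3.93 ± 0.84). BSC1 and YHL018W were at 0 in quiescent replicate 1. The largest decreases at 240 min were those of snR14, SPG4 (-5.75 ± 1.06) and BI4, a maturase that overlaps COB in the mitochondrial genome (36540 to 42251, plus strand), and in log phase those of YAR035C-A, ADY2 and YAT1 (-9.27 ± 0.45).

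Against quiescent cells, 134 of 138 ribosomal protein genes were higher at 240 min (135 adjusted over the list alone; median 2.12, adjusted p = 7.81e-26) and 120 higher and 1 lower in log phase (122 and 1 adjusted over the list alone; median 1.94, adjusted p = 6.48e-23). With an estimated correlation these had adjusted p = 0.0563 and adjusted p = 0.0775. Ribosome biogenesis had 125 of 135 higher and 2 lower at 240 min (125 and 2 adjusted over the list alone; median 1.83, adjusted p = 4.37e-23), and 86 higher and 5 lower in log phase (86 and 5 adjusted over the list alone; median 0.98, adjusted p = 4.81e-10). With an estimated correlation these had adjusted p = 0.178 and adjusted p = 0.285. In log phase its medians were 1.59 within replicate 1 and 0.70 within replicates 2 and 3. Of the 29 lists 18 were called at 240 min and 17 in log phase, and with an estimated correlation only those of translation and β-oxidation, neither of which was called with the block as well. Of 54 translation genes 50 were higher and 1 lower at 240 min (50 and 1 adjusted over the list alone; adjusted p = 6.38e-15, and 0.0337 with an estimated correlation) and 49 and 1 in log phase (49 and 1 adjusted over the list alone; 1.38e-13, and 0.0412 with an estimated correlation). Of 15 β-oxidation genes 13 were lower at 240 min (13 lower and 1 higher adjusted over the list alone; 2.77e-07, and 0.0337 with an estimated correlation) and 12 in log phase (12 adjusted over the list alone; 2.46e-07, and 0.0412 with an estimated correlation). With the block and an estimated correlation adjusted p was 0.150 for both at 240 min, and 0.119 for translation and 0.117 for β-oxidation in log phase. Of 25 acetate genes 24 were lower at 240 min (24 adjusted over the list alone; median -3.86, adjusted p = 2.88e-12, and adjusted p = 0.181 with an estimated correlation) and 23 in log phase (23 adjusted over the list alone; median -4.62, adjusted p = 1.38e-13, and adjusted p = 0.127 with an estimated correlation).

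Stress genes were lower than in quiescent cells at 240 min (30 of 39, 1 higher; 30 and 1 adjusted over the list alone; median -2.23, adjusted p = 3.84e-07, and adjusted p = 0.295 with an estimated correlation). In log phase 19 were lower and 6 higher (19 and 6 adjusted over the list alone; median -1.13, adjusted p = 0.0236, and adjusted p = 0.652 with an estimated correlation), with medians of -2.07 within replicate 1 and -0.49 within replicates 2 and 3. Without log-phase replicate 1 the log-phase call was lost (adjusted p = 0.440), as were those of the histones (0.0862) and the G2/M cluster (0.0943). The trehalose and glycogen list was not called in log phase (adjusted p = 0.551), at -1.57 within replicate 1 and 0.22 within replicates 2 and 3. The histone list had a median of 1.18 at 240 min (4 of 11 higher; adjusted p = 0.0828, and 0.0243 with the block, but 0.182 with the block and an estimated correlation). EAF3 changed by -3.03 ± 0.25 at 240 min and HDA1 by 1.60 ± 0.24 in log phase, while neither histone acetylation list was called (adjusted p = 0.923 and 0.529 at 240 min, 0.551 and 0.524 in log phase).

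Of the genes called in log phase against quiescent cells, 798 of 1691 higher (47.2%) and 940 of 1635 lower (57.5%) were called the same way at 30 min, and 64 and 39 the opposite way. At 240 min the shared calls were 1362 (80.5%) and 1387 (84.8%), with 4 and 2 opposite. Independent lists of these sizes would share 349 and 388 at 30 min and 492 and 483 at 240 min. In 100 simulated draws with unchanged groups and a simulated quiescent group common to both comparisons, 0 calls were shared. These draws hold no effects and so yield hardly any calls. Their 0 therefore does not measure how many shared calls come from the common quiescent libraries. Across genes, which are not independent replicates, fold changes against quiescent cells at 30 min and in log phase correlated at 0.633 (0.499 simulated), with a covariance of 0.939 (0.0520 simulated). For 240 min and log phase the correlation was 0.902 (0.501 simulated) and the covariance 1.82 (0.0523 simulated). The 3 quiescent libraries cannot be split into parts with several libraries each, so part of the shared calls may come from these libraries.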

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

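No called value of a named gene and no called list changed direction in any fit with replicates. Within replicate 1, where nothing can be tested, the medians of 3 lists called higher in log phase than at 240 min were at -0.55 (trehalose), -0.10 (autophagy) and -0.00 (mitotic exit). Of all called genes, 99.94% at 240 min against 30 min and 99.79% in log phase against quiescent cells had the same sign with total-count scaling. In every other fit with replicates it was 100%. Within replicate 1 alone, 96.35% of genes called higher and 98.33% of those called lower in log phase against 240 min kept their direction. In the other comparisons 98.64% to 100% did, though the genes were chosen from these same libraries. Of 9318 tests of 550 called values of named genes, 8840 kept the call and 478 lost it. Those genes were mostly named for large called changes, and a pseudocount of 5 or no filter changed none of their calls. A high share kept was therefore likely beforehand. An estimated correlation ended the call of 66 of 79 list results. With the replicate block and an estimated correlation 77 of the 79 were lost, and those left were the ribosomal proteins (adjusted p = 0.0462) and meiosis (0.0270) at 240 min against 30 min. The settings with edgeR, with replicates 2 and 3 alone, and with both the block and an estimated correlation were chosen only after the results were seen. The replicate block by itself ended the call of CLB6 at 240 min against 30 min (adjusted p = 0.0492, then 0.0508) and, apart from the calls given in the report, changed no other list or always-named gene.

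Replicates 2 and 3 alone gave 1933 genes higher and 2261 lower at 30 min against quiescent cells, 1777 and 1782 at 240 min against 30 min, 1872 and 1801 in log phase against 240 min, and 2659 calls shared by 30 min and log phase (1738 in the test with all libraries). Total-count scaling gave 328 and 1941 at 240 min against 30 min, 112 and 693 in log phase against 240 min, 978 higher in log phase than in quiescent cells, and 215 transient genes. With edgeR and the block the counts were 1184 and 1263 at 240 min against 30 min and 681 and 495 in log phase against 240 min. For log phase against 240 min DESeq2 gave 501 and 418, the replicate block 544 and 522, and a model of only the 2 groups compared 6 and 13. The block gave 1550 higher and 1799 lower for 30 min against quiescent cells, and 1155 and 1159 for 240 min against 30 min. Against quiescent cells it gave 2010 and 1991 at 240 min, and 2024 and 1895 in log phase. With 1 library left out, 240 min against 30 min gave 516 to 649 higher and 495 to 652 lower, and log phase against 240 min 19 to 1108 higher and 29 to 968 lower.

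Some list calls ended under other settings. At 30 min against quiescent cells mitotic exit had adjusted p = 0.0798 with DESeq2, 0.137 with replicates 2 and 3 alone and 0.0531 with edgeR and the block. At 240 min against 30 min mitochondrially encoded RNA had 0.0838 with total-count scaling, 0.0808 with DESeq2, 0.0548 with only the 2 groups and 0.123 with replicates 2 and 3 alone. At 240 min against quiescent cells DESeq2 gave 0.0882 for the citric acid cycle and 0.115 for G1/S. In log phase against 240 min, replicates 2 and 3 alone gave adjusted p = 0.204 for acetate use, 0.351 for mating, 0.187 for methionine, 0.103 for mitochondrially encoded RNA and 0.0985 for mitotic exit and meiosis. Meiosis had 0.0646 with total-count scaling, and mitotic exit 0.0513 with TMM, 0.0582 at a minimum mean of 100, 0.0695 with DESeq2, 0.0971 with edgeR and 0.0532 with edgeR and the block. In log phase against quiescent cells the stress list had 0.0822 with total-count scaling, 0.0546 with DESeq2 and 0.603 with replicates 2 and 3 alone, where the G2/M cluster had 0.106. An estimated correlation was not run on replicates 2 and 3 alone. With 2 libraries per group and the preset correlation they also called 10 lists that the test with all libraries did not. At 240 min against 30 min these were ribosome biogenesis (0.00428), polymerases I and III (0.00986), proteasome (0.00513), trehalose (0.0347), hexose transporters (0.0460) and the G2/M cluster (0.0477). In log phase against 240 min they were G1/S (4.13e-05), ribosomal proteins (0.0158) and translation (0.0238), and at 240 min against quiescent cells the histones (0.0134).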

Other observations

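The chaperone and nitrogen lists, and all explanations weighed below with their tests, were chosen only after the results were seen. The camera p-values of these 2 lists were adjusted over the 2 alone and not over the 29 fixed lists. They are therefore less strict than those of the fixed lists and cannot be ranked against them. Chaperone genes rose in the first 30 min of exit and fell by 240 min. Of 32 cytosolic and mitochondrial chaperone genes, 22 rose and 1 fell between quiescence and 30 min (23 and 2 adjusted over the list alone; median 1.53, adjusted p = 8.26e-07, and adjusted p = 0.169 with an estimated correlation). Between 30 min and 240 min 1 rose and 18 fell (1 and 21 adjusted over the list alone; median -1.34, adjusted p = 4.19e-09, and adjusted p = 0.104 with an estimated correlation). SIS1, an Hsp40 co-chaperone gene, was at 2268 ± 533 in quiescent cells, 18522 ± 3460 at 30 min and 4574 ± 2096 at 240 min, HSP78 at 2292 ± 127, 12702 ± 1308 and 2091 ± 617, and the disaggregase gene HSP104 at 11028 ± 2859, 34812 ± 4120 and 9144 ± 2861. The Hsp90 gene HSP82 was not called at 30 min (1.44, adjusted p = 0.0708). Of the 32 genes, 10 were transient.

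Genes under nitrogen catabolite repression, which yeast shuts off when a preferred nitrogen source is present, fell between 30 min and 240 min. Of 30 genes 2 rose and 19 fell (2 and 21 adjusted over the list alone; median -1.18, adjusted p = 1.72e-07, and adjusted p = 7.78e-04 with an estimated correlation, or 0.00606 with the replicate block as well). In the first 30 min 4 rose and 12 fell (adjusted p = 0.175). MEP2 was at 9171 ± 2347 in quiescent cells, 11670 ± 1275 at 30 min and 1060 ± 356 at 240 min. DAL80, a repressor gene of this regulon, fell by 2.48 from 30 min to 240 min and from 228 ± 53.1 at 240 min to 40.1 ± 13.3 in log phase.

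Stress and storage genes differed between log-phase replicate 1 and replicates 2 and 3, with a median log2 difference of 1.53 over 56 genes and 50 of them above 0. A batch difference common to all time points would give the same sign elsewhere, but the medians were -0.22 in quiescent cells, -0.0455 at 30 min and -0.52 at 240 min, which argues against it. Log-phase replicate 1 could be a mislabelled 240 min library, and across genes it correlated at 0.965 with 240 min replicate 1 but at 0.890 and 0.896 with log-phase replicates 2 and 3. Its acetate list, however, stood at a median of -1.27 relative to the 240 min mean, with 20 of 25 genes below all 240 min libraries, which argues against this. Log-phase replicates 2 and 3 may have come from cultures nearer to glucose exhaustion. In these the respiratory chain list was at 0.37 and ribosome biogenesis at -0.53 relative to replicate 1, but the citric acid cycle list was at -0.0922 with quartiles of -0.458 to 0.363, and culture densities are not given in the sources used here, so this stays open.

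The rise of chaperone genes at 30 min might come from the shallow quiescent replicate 1. Without that library the median of the list was 1.47, which argues against it. A rise of all stress genes is argued against as well, since the 31 genes of the stress list that are not chaperones had a median of -1.34. Pelleting and washing could raise chaperone genes by themselves. The number of libraries of washed cells without new medium was 0, so this stays open.

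RNA without a poly(A) tail, or with a short one, took a larger share of quiescent libraries. Mitochondrial genes held 0.0499 ± 0.0152% of the reads in quiescent cells and 0.0119 ± 0.00365% at 30 min, and small nuclear and nucleolar RNA genes 0.512 ± 0.0210% and 0.272 ± 0.0763%. The shallow replicate 1 could have caused this, but the lower mitochondrial share of quiescent replicates 2 and 3 was 0.0488% against at most 0.0143% at 30 min, which argues against it. Weaker poly(A) selection in quiescent libraries would lower the class as a whole at both later times. By 240 min 33 of 76 small nuclear and nucleolar RNA genes were lower and 6 higher, with a median of -0.79, but at 30 min the median was -0.27 with quartiles of -1.18 to 0.362 and 30 genes above 0, so this stays open. Less messenger RNA per quiescent cell could do the same, and with 0 spike-in features in the table it cannot be told apart from weaker selection. The falls of these RNAs are therefore not read as regulation. Falls and rises of other genes are likewise relative to the genes tested and are not amounts per cell.

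For each comparison the 6 libraries were also split in all 10 ways into 3 and 3, and 10 splits are too few for a share under 0.05. The real split had the most calls in each, so the number of splits with as many was 1. It gave 2605 calls for 30 min against quiescent cells, 1602 for 240 min against 30 min, 432 for log phase against 240 min, 3442 for 240 min against quiescent cells and 3326 for log phase against quiescent cells. The highest other split had 61 in log phase against 240 min, where it grouped log-phase replicate 1 with 240 min replicates 2 and 3, and 0 by limma in the others. The real split is 1 of 4 that part all 3 pairs of equal replicate number, and the split with 61 calls is another.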
